A study of Mus musculus with 16 samples.

How the data were processed

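MicroRNA (miRNA) levels were measured in liver RNA of 16 samples from male C3H mice, 4 in each of 4 groups formed by genotype and diet. Genotype was wild type (WT) or a hepatocyte-specific knockout of Ctnnb1 (CTNNB1KO), made by albumin-promoter Cre recombinase acting on a floxed gene. Diet was free of phenobarbital or held 0.05% phenobarbital for 12 weeks. The labels call the control agent water while the treatment protocol describes a phenobarbital-free diet, so these samples are called controls. Groups and replicate numbers were taken from the sample titles and group labels. Nothing in the labels states outright that each array came from a separate animal, so p-values measure the spread between these samples, which may in part be technical.

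The deposited values are log2 expression values per miRNA feature and array in 1 table of 650 features. Per the labels' protocols, 100 ng of total RNA was labelled with an Agilent miRNA kit for single-channel arrays after RNA integrity had been checked. Per the submitters' processing notes, RMA and limma were used by the authors, and their versions, the background step and any filter are not given in the sources used here. The same highest log2 value recurred on 5 of the 16 arrays, including all 4 WT control arrays, while the other arrays had slightly different maxima. RMA as usually run scales arrays to each other, so a shift of most miRNAs in one direction may have been removed from these values. Scanner intensities, detection calls and slide positions were not used here, so the number of arrays sets the precision and slide could not be entered as a block.

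Of the 650 features, 611 were mouse miRNAs and 39 were miRNAs of mouse cytomegalovirus (29) and mouse gammaherpesvirus (10). The viral features served as a background reference: the 0.95 quantile of their mean log2 values, 3.98, was taken as the dim floor. The viral means had a median of 3.23 and a maximum of 4.60, and 2 of them lay above the floor. Mean values above the floor in at least 1 group were found for 141 mouse miRNAs. For named miRNAs that passed between 2 groups, where every array of the dimmer group lay at or under the floor and the brighter group's mean above it, the fold is also given as a lower bound, that mean against the floor. miRNA names are those of the array design, in which an asterisk marks the opposite arm of the hairpin and an unmarked name the arm then taken as the main product. Gene order between Dlk1 and Dio3 came from a RefSeq gene table of GRCm38.p6, used for names and order only.

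The tests were fixed before the data were examined. A linear model with 1 mean per group was fitted to the deposited log2 values of all 611 mouse miRNAs and all 16 arrays with limma 3.58.1 in R 4.3.3, which leaves 12 residual degrees of freedom. Standard errors and p-values were moderated with eBayes and an intensity trend, and adjusted by Benjamini-Hochberg over the 611 miRNAs at a threshold of 0.05. Each miRNA's spread was pooled over the 4 groups. Where groups differ in spread, a standard error can be too large or too small for the 2 groups compared. All tests were two-sided. The 5 contrasts were phenobarbital against control in WT, the same in CTNNB1KO, CTNNB1KO against WT in controls, the same under phenobarbital, and the interaction, which is the phenobarbital effect in CTNNB1KO minus that in WT. The words rose and fell are used only of miRNAs or lists that passed.

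Named miRNAs followed a rule set in advance. It took the 12 largest differences per direction among those that passed and lay above the floor in the higher group, up to 4 members that passed from each list, the 3 smallest p-values per direction where none passed, and 12 miRNAs of prior interest. The 19 lists were written in advance. They held the Dlk1-Dio3 cluster, the miR-200 family, the miR-183, miR-96 and miR-182 cluster, the Sfmbt2 cluster, the let-7 family, miR-17 and miR-92 paralogs, miR-34 (p53 targets), liver-tumour associated miRNAs, the miR-29 family, the miR-99, miR-100 and miR-125 families and hepatocyte-abundant miRNAs. Markers of leukocytes, erythroid cells, endothelium, stellate or mesenchymal cells, biliary or other epithelium, striated muscle, exocrine pancreas and neural tissue made up the rest. Some miRNAs stood in more than 1 list, such as miR-31 among epithelial markers and liver-tumour associated miRNAs. Lists of at least 3 measured members were tested with camera at a preset correlation of 0.01 and adjusted over the 18 lists tested; the endothelial list had 2 members and was not tested. The means of the 12 Dlk1-Dio3 members above the floor and of all 75 members were compared between groups by an exact permutation test, for which 4 against 4 arrays allow no p under 0.0286.

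The procedure was tested on simulated data for the phenobarbital contrast in WT with 611 features, in which 18 of 20 changes of 0.5 on the log2 scale and all 20 changes of each of 1 and 2 were recovered with 3 false calls. This was a single draw of independent noise with the same SD in every group. It left out shared variation of cluster members, unequal group spreads and background, so error rates in the real data may be higher. Alternatives covered the variance model, robust moderation, array weights, an unmoderated linear model, a fit on the contrast's own groups, other between-array scalings, a soft floor standing in for another background treatment, a filter on dim miRNAs, the replicate number as a block, other list tests and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.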

Results

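The study profiled miRNAs in mouse liver to ask how 12 weeks of dietary phenobarbital, an activator of the nuclear receptor CAR and a promoter of liver tumours in mice, changed miRNA levels with and without beta-catenin in hepatocytes. Ctnnb1 encodes beta-catenin, the transcriptional co-activator of the Wnt pathway that maintains the perivenous gene programme of the liver. The 4 groups of 4 arrays were WT controls, WT with phenobarbital, CTNNB1KO controls and CTNNB1KO with phenobarbital. A miRNA array does not measure Ctnnb1 mRNA, so the knockout itself was not checked here. CTNNB1KO phenobarbital replicate 4 had 100 miRNAs over the dim floor of 3.98, and every other array had at least 114. Arrays of one group correlated with each other between 0.966 and 0.996 across miRNAs. The hepatocyte miRNA miR-122 was the brightest feature in the WT controls, at 15.28 on each of the 4 arrays and also on CTNNB1KO phenobarbital replicate 3. With no spread among the controls, the differences of miR-122 given below are not taken as measures of its level.

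In WT livers, phenobarbital raised a set of miRNAs from the imprinted Dlk1-Dio3 region, a large miRNA cluster expressed from the maternal chromosome and mostly silent in adult liver, and raised the liver miRNA miR-802. miR-376b rose from 3.48 ± 0.11 to 5.62 ± 0.27 (mean log2 value ± SD, n = 4 arrays per group), a log2 difference of 2.14 ± 0.15 (SE; limma adjusted p = 1.21e-08) and at least 3.10-fold against the dim floor. miR-154* rose by 1.74 ± 0.20 (adjusted p = 1.78e-05), at least 2.55-fold, and miR-127 by 1.25 ± 0.16 (adjusted p = 4.13e-05), at least 1.66-fold. miR-802, a regulator of hepatic glucose metabolism, rose from 5.57 ± 0.27 to 6.96 ± 0.19, a difference of 1.38 ± 0.23 (adjusted p = 0.000827). For each of these 4 miRNAs, all 4 phenobarbital arrays lay above all 4 control arrays.

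Of all mouse miRNAs tested, 17 rose and none fell in this comparison, while 46 had an unadjusted p under 0.05. Of the 17, 16 belonged to the Dlk1-Dio3 list. Besides those above, miR-377 rose by 0.97 ± 0.13, miR-379 by 0.96 ± 0.14, miR-299* by 0.84 ± 0.15, miR-136 by 0.76 ± 0.14 and miR-376a by 0.69 ± 0.10. Smaller rises were measured for miR-300 (0.61 ± 0.12), miR-434-3p (0.61 ± 0.12), miR-154 (0.59 ± 0.14), miR-411 (0.59 ± 0.10) and miR-541 (0.29 ± 0.07), and the remaining 3 members lay between 0.38 and 0.51. The WT control means of these 16 members lay under the dim floor, so their log2 differences are set in part by background. Against the floor the rises were at least 1.36-fold for miR-136, 1.34-fold for miR-377, 1.32-fold for miR-379, 1.28-fold for miR-299* and 1.18-fold for miR-154, and at least 1.02-fold for miR-376a and miR-300 and 1.01-fold for miR-434-3p. For miR-411, miR-541 and the remaining 3 the phenobarbital means also lay under it (3.62 to 3.93). In the gene order of the reference, all 16 lay between Dlk1 and Dio3, an interval that held 77 of the measured features (Fisher's exact test p = 1.42e-14, across features that share transcripts and are not independent).

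**Figure D1:**
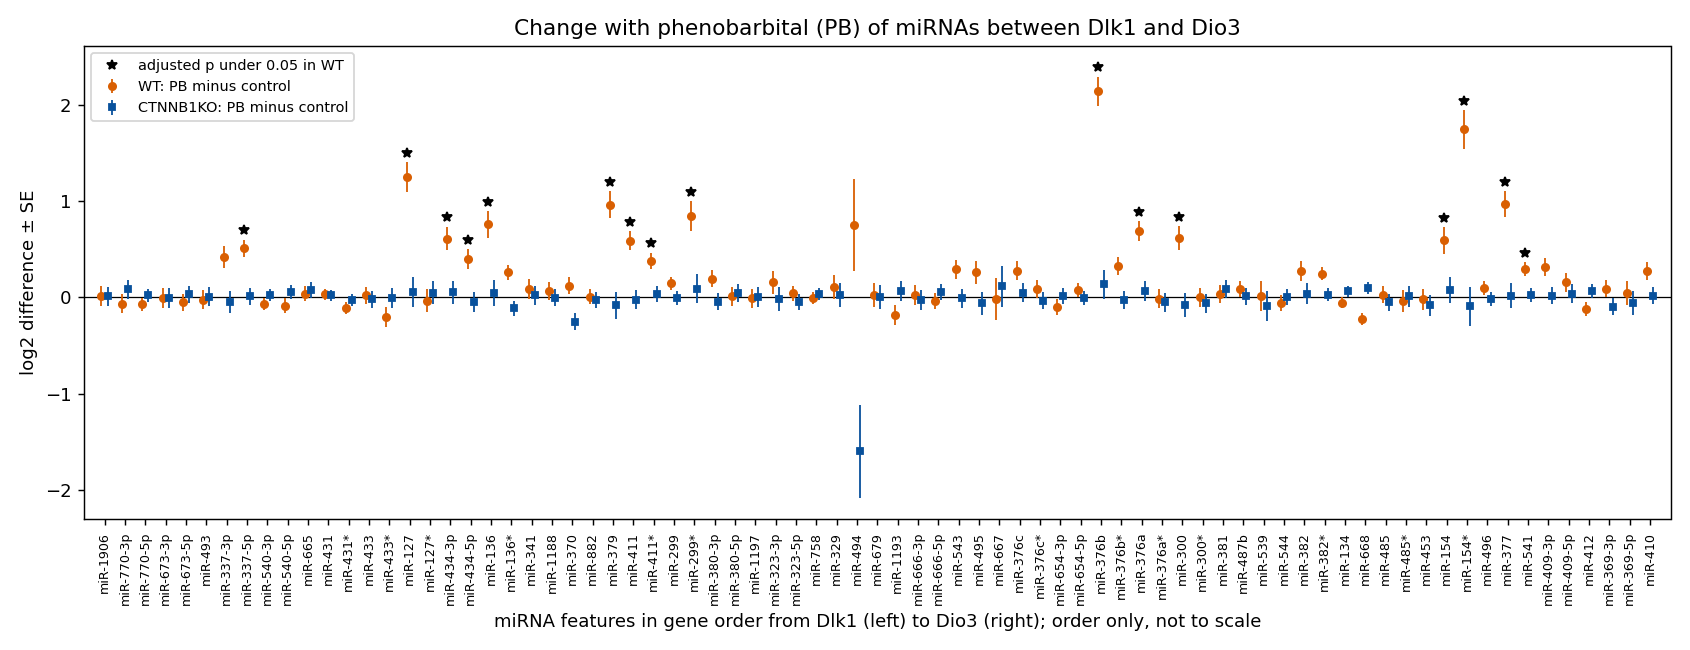
Log2 difference (phenobarbital minus control, ± SE from limma, n = 4 arrays per group) of each measured miRNA feature between Dlk1 and Dio3, in gene order, for WT livers (orange circles) and CTNNB1KO livers (blue squares), with stars over the 16 features that passed in WT. miR-376b reached 2.14 in WT and 0.14 in CTNNB1KO, while miR-494 lay apart from its neighbours at 0.75 and -1.60 (-0.95 without CTNNB1KO control replicate 3).

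As a list, the Dlk1-Dio3 miRNAs rose in WT (camera adjusted p = 6.67e-13; adjusted p = 0.00144 with an estimated correlation). Of its 75 measured members, 16 rose and 59 did not pass; adjusted over the list alone, 24 were higher and 1 was lower. All 75 members, most of them dim, averaged 3.59 ± 0.06 with phenobarbital and 3.36 ± 0.01 in controls (SD, n = 4), a difference of 0.23 (exact permutation p = 0.0286, the smallest possible; 0.0571 after adjustment over 4 comparisons). The 12 members above the floor averaged 4.74 ± 0.31 against 3.75 ± 0.09, a difference of 0.99. Of these 12, 11 passed the floor in the WT phenobarbital group alone, so the rise itself in part chose them. miR-494, the brightest member, differed by 0.75 ± 0.48 and did not pass.

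None of the other 17 lists passed in WT. The closest were the let-7 family and the miR-17 and miR-92 paralogs (adjusted p = 0.0752 for each), followed by the erythroid markers (adjusted p = 0.405). The adjusted p was 0.537 for the miR-200 family, the miR-183, miR-96 and miR-182 cluster, the Sfmbt2 cluster, miR-34, liver-tumour associated miRNAs, the miR-29 family and the stellate, biliary, muscle and pancreas markers. It was 0.641 for neural markers, 0.691 for hepatocyte-abundant miRNAs and for the miR-99, miR-100 and miR-125 families, and 0.788 for leukocyte markers. Among single miRNAs, miR-21 differed by -0.82 ± 0.28 (adjusted p = 0.213), miR-122 by -0.09 ± 0.05, miR-200a by 0.06 ± 0.16, miR-200b by 0.04 ± 0.17, miR-429 by -0.05 ± 0.13, miR-375 by 0.07 ± 0.10, miR-182 by -0.03 ± 0.08 and miR-34a by 0.02 ± 0.48. The standard error of miR-34a reflects the spread pooled over all groups. Its SD was 0.16 in WT controls and 0.08 in WT with phenobarbital, against 1.47 and 0.71 in the CTNNB1KO groups. With array weights 29 miRNAs passed, 24 higher and 5 lower. The calls of miR-154 and miR-541 ended when any of 6 and 7 single arrays were left out (highest adjusted p = 0.0763 and 0.159).

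In CTNNB1KO livers, no miRNA passed in the comparison of phenobarbital with control. The smallest limma adjusted p was 0.467, 32 miRNAs had an unadjusted p under 0.05 (16 in each direction), and none passed with array weights or an unmoderated linear model. The Dlk1-Dio3 miRNAs showed no rise: miR-127 differed by 0.05 ± 0.16, miR-411 by -0.03 ± 0.10 and miR-541 by 0.02 ± 0.07. All 75 cluster members averaged 3.33 ± 0.02 with phenobarbital and 3.35 ± 0.02 in controls (exact permutation p = 0.286, n = 4), and the list had a camera adjusted p of 0.825. Over the 12 members above the floor the mean differed by -0.11 (exact permutation p = 0.114) and the median by 0.017. The mean difference rests on miR-494 (-1.60). The other 11 differed by -0.10 to 0.14 and lay under the floor in both CTNNB1KO groups. miR-802 stood at 6.95 ± 0.23 against 6.23 ± 0.58, a difference of 0.72 ± 0.23 that did not pass (adjusted p = 0.562) although all 4 phenobarbital arrays lay above all 4 controls. Without control replicate 2, at 5.38, that difference was 0.43.

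The miRNAs with the smallest p-values in CTNNB1KO livers were, besides miR-802, miR-16 (0.42 ± 0.14, and 0.28 without control replicate 2) and miR-133b (1.79 ± 0.61, and 0.89 without phenobarbital replicate 1) among the higher ones and miR-30d (-0.59 ± 0.16), miR-689 (-0.92 ± 0.25) and miR-494 (-1.60 ± 0.48, and -0.95 without control replicate 3) among the lower ones. miR-34a, a transcriptional target of p53, differed by 1.36 ± 0.48 (adjusted p = 0.562). miR-21 (0.03 ± 0.28), miR-122 (0.08 ± 0.05), miR-200a (-0.03 ± 0.16), miR-200b (-0.14 ± 0.17), miR-429 (0.09 ± 0.13), miR-182 (0.03 ± 0.08) and miR-375 (-0.10 ± 0.10) did not pass either. Of the lists, the striated muscle markers rose (camera adjusted p = 0.0014; adjusted p = 0.654 with an estimated correlation), with 0 of 8 members passing singly and 0 adjusted over the list alone. Replicates 1 and 2 of this group carried the muscle miRNAs miR-1 (8.17 and 6.03), miR-133b (7.74 and 5.69) and miR-133a (6.46 and 4.98), whereas miR-1 did not exceed 3.86 on any other array. The other 17 lists did not pass, the closest being hepatocyte-abundant miRNAs (adjusted p = 0.237; adjusted over the list alone 1 member was lower).

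Without the 2 muscle-bearing arrays, an alternative chosen after seeing the data, the muscle list's mean difference was -0.03, and the leukocyte miRNA miR-142-5p alone passed (1.33 ± 0.23, limma adjusted p = 0.011), at 5.92 and 5.99 on the 2 arrays kept, which had the higher leukocyte means, and at 4.63 and 4.75 on those left out. Without CTNNB1KO control replicate 2, in which miR-34a stood at 9.41, miR-34a rose with phenobarbital by 2.09 ± 0.26 (limma adjusted p = 0.000187); across the other single arrays left out its adjusted p lay between 0.54 and 0.998.

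The genotype comparison in controls asked what loss of Ctnnb1 changed without phenobarbital. CTNNB1KO livers had more miR-34a, at 7.21 ± 1.47 against 4.95 ± 0.16 (log2 mean ± SD, n = 4), a difference of 2.25 ± 0.48 (limma adjusted p = 0.0283), and more miR-31*, the opposite arm of the epithelial miRNA miR-31, which rose by 1.05 ± 0.17 (adjusted p = 0.00226). They had less of the red-cell miRNAs miR-451, which fell by 1.78 ± 0.26 (adjusted p = 0.00128), and miR-144, which fell by 1.84 ± 0.32 (adjusted p = 0.00378). miR-25, from a cluster inside the replication gene Mcm7, fell by 0.52 ± 0.12 (adjusted p = 0.0428). In all 5 the 4 arrays of one genotype lay apart from the 4 of the other. These 5 were the only mouse miRNAs to pass (2 higher, 3 lower), with 49 at an unadjusted p under 0.05.

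The erythroid markers fell as a list in CTNNB1KO controls (camera adjusted p = 4.28e-09; adjusted p = 0.0169 with an estimated correlation): 2 of 3 members fell, and 3 adjusted over the list alone, miR-486 being the one that passed there only (-0.62 ± 0.20). The miR-17 and miR-92 paralogs also fell (camera adjusted p = 0.00649; adjusted p = 0.334 with an estimated correlation), with 1 of 20 members passing and 3 adjusted over the list alone, miR-25, miR-106b (-0.47 ± 0.13) and miR-19a (-0.69 ± 0.19). The leukocyte markers did not pass (camera adjusted p = 0.0504), nor did the miR-29 family (adjusted p = 0.0541). Leukocyte members above the floor averaged 5.77 ± 0.68 against 5.17 ± 0.14. Camera passed the leukocyte list on median-centred arrays (adjusted p = 0.0296) and among miRNAs above the floor (0.0399). It also passed without the 2 muscle-bearing arrays described above (0.0141), a choice made after seeing the data. The list did not pass with an estimated correlation (0.365), fry (0.183) or the replicate block. Of the biliary or epithelial markers, miR-31* rose and 14 members did not pass (list adjusted p = 0.158). Adjusted over the list alone 2 were higher. This list passed with fry (adjusted p = 0.0436) and with camera among miRNAs above the floor (0.0399), but not with an estimated correlation (0.365) or the replicate block. None of the 75 Dlk1-Dio3 members passed, and their mean differed by -0.01 (exact permutation p = 0.429, n = 4). Of the 12 members above the floor in some group, 11 passed it in WT with phenobarbital alone and lay under it in both control groups. These 11 were lower in CTNNB1KO and miR-494 was higher (1.07, and 0.42 without CTNNB1KO control replicate 3). The mean of the 12 was 3.67 ± 0.10 against 3.75 ± 0.09 (exact permutation p = 0.229). Their per-array median differed by -0.21 (exact permutation p = 0.0286, the smallest possible and not adjusted). That is a difference between background values and does not show a change of the cluster.

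The remaining named miRNAs did not pass between genotypes in controls: miR-802 differed by 0.66 ± 0.23 (adjusted p = 0.354; 0.94 and 0.00364 without CTNNB1KO control replicate 2), miR-122 by -0.13 ± 0.05, miR-21 by -0.15 ± 0.28, miR-127 by -0.24 ± 0.16, miR-200a by 0.09 ± 0.16, miR-200b by 0.34 ± 0.17 and miR-375 by 0.14 ± 0.10. The miR-34a mean rested in part on CTNNB1KO control replicate 2 at 9.41, the other 3 lying between 6.35 and 6.65. Without that array the difference was 1.52 (limma adjusted p = 0.00276). Without any 1 WT control array 3 miRNAs passed and miR-34a did not (adjusted p from 0.068 to 0.12). It did not pass under 5 of 11 other settings (highest adjusted p = 0.195), and miR-25 lost its call without any of 14 single arrays (highest 0.206).

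Under phenobarbital, CTNNB1KO livers had far more miR-34a than WT livers, at 8.56 ± 0.71 against 4.97 ± 0.08 (log2 mean ± SD, n = 4), a rise of 3.59 ± 0.48 (limma adjusted p = 5.36e-05). miR-142-5p, a miRNA of blood cells, rose by 1.09 ± 0.28 (adjusted p = 0.0267) and miR-31* by 0.77 ± 0.17 (adjusted p = 0.00962). Dlk1-Dio3 miRNAs were lower in CTNNB1KO: miR-376b fell by 2.22 ± 0.15, at least 3.10-fold, miR-154* by 2.06 ± 0.20, at least 2.55-fold, and miR-127 by 1.43 ± 0.16, at least 1.66-fold. The red-cell miRNA miR-144 fell by 1.35 ± 0.32 (adjusted p = 0.0174), and miR-689 fell by 1.10 ± 0.25 (adjusted p = 0.0103). In all, 3 miRNAs rose and 20 fell, 18 of them in the Dlk1-Dio3 list, with 85 at an unadjusted p under 0.05.

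**Figure D2:**
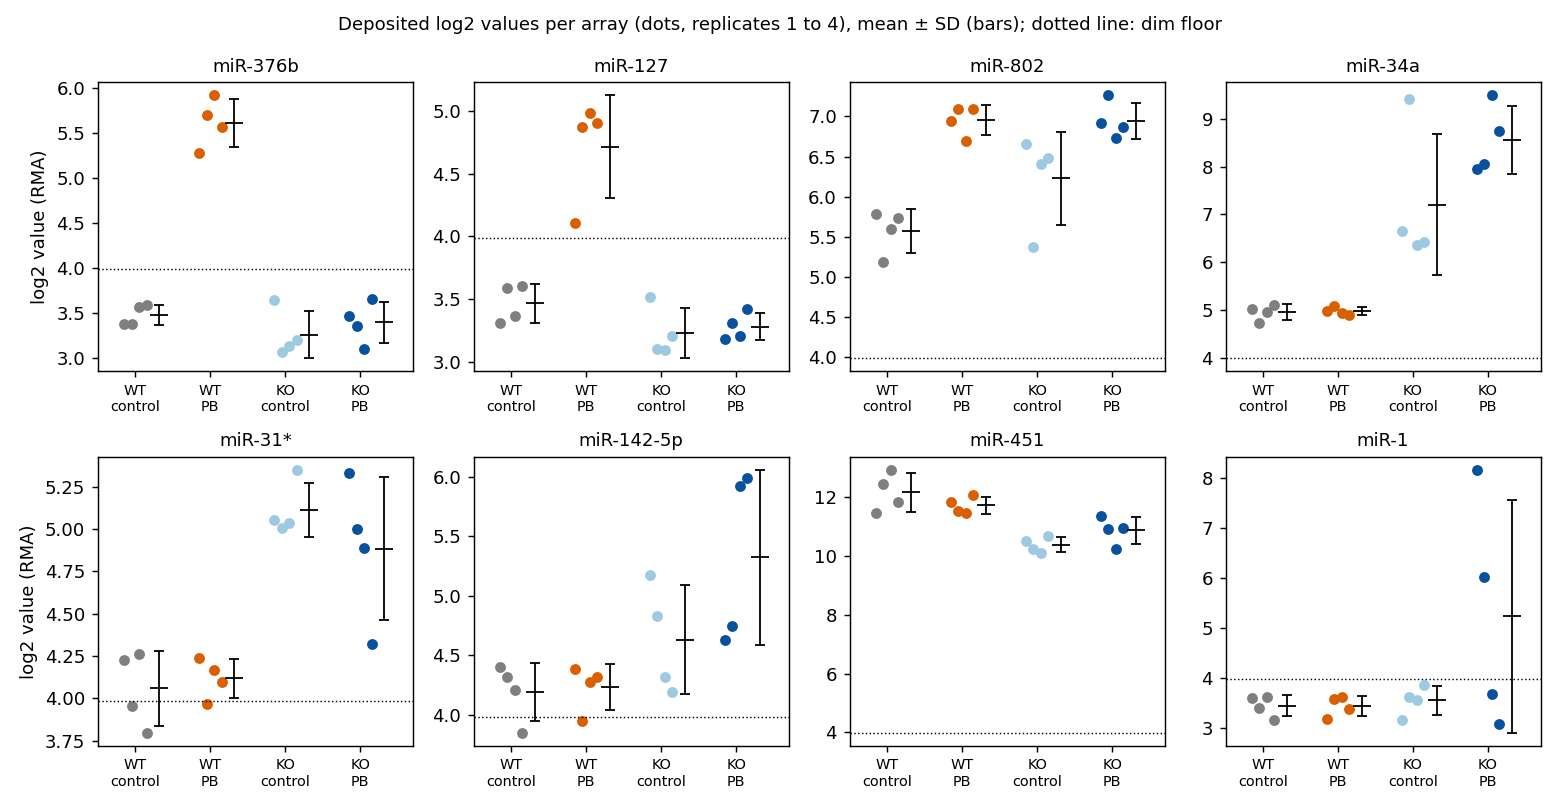
Deposited log2 values of 8 miRNAs on each array (dots, replicates 1 to 4 from left to right) with the group mean ± SD (n = 4), for WT and CTNNB1KO (KO) livers without and with phenobarbital (PB); the dotted line is the dim floor of 3.98. miR-376b averaged 5.62 in WT with phenobarbital and 3.48, 3.26 and 3.39 elsewhere, miR-34a averaged 7.21 and 8.56 in the CTNNB1KO groups, and miR-1 exceeded the floor on 2 arrays.

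Among the Dlk1-Dio3 members that fell in this comparison were also miR-377 (-1.11 ± 0.13), miR-379 (-1.08 ± 0.14), miR-299* (-1.04 ± 0.15), miR-136 (-1.02 ± 0.14), miR-154 (-0.85 ± 0.14), miR-300 (-0.73 ± 0.12), miR-434-3p (-0.70 ± 0.12), miR-411 (-0.63 ± 0.10) and miR-541 (-0.30 ± 0.07). Except for miR-411 and miR-541, under the floor in every group, the lower bounds of their folds were those given for the rises in WT, since the brighter group was the same. As a list they fell (camera adjusted p = 1.28e-11; adjusted p = 0.00238 with an estimated correlation), with 18 of 75 members lower, 7 of them under the floor in every group, and 57 not passing, and 24 lower adjusted over the list alone. The mean of all 75 members was 3.33 ± 0.02 against 3.59 ± 0.06 (exact permutation p = 0.0286, n = 4, the smallest possible; 0.0571 over 4 comparisons), and that of the 12 members above the floor 3.56 ± 0.06 against 4.74 ± 0.31. The WT phenobarbital arrays also entered the comparison of phenobarbital with control in WT, so the 2 results on this cluster are not independent.

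Markers of other cell types also moved with genotype under phenobarbital. The leukocyte markers rose (camera adjusted p = 0.0116; adjusted p = 0.211 with an estimated correlation): 1 of 11 members passed, and 4 adjusted over the list alone, namely miR-142-5p, miR-142-3p (1.42 ± 0.43), miR-223 (1.38 ± 0.44) and miR-342-3p (0.50 ± 0.16). The erythroid markers fell (adjusted p = 0.0116; adjusted p = 0.211 with an estimated correlation), with 1 of 3 passing and 2 adjusted over the list alone, miR-144 and miR-451 (-0.86 ± 0.26). The stellate or mesenchymal markers rose (adjusted p = 0.0303; adjusted p = 0.211 with an estimated correlation) with 0 of 13 members passing and 0 adjusted over the list alone. The biliary or epithelial markers rose (adjusted p = 0.0303; adjusted p = 0.126 with an estimated correlation), with 1 of 15 passing and 2 adjusted over the list alone, miR-31* and miR-31 (0.91 ± 0.26). The miR-34 list rose (adjusted p = 0.0367; adjusted p = 0.229 with an estimated correlation) through miR-34a, its 1 member above the floor.

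Among the other lists under phenobarbital, hepatocyte-abundant miRNAs and muscle markers came closest (adjusted p = 0.0742 for each; adjusted over the list alone 3 muscle members were higher), and the untested endothelial miRNAs miR-126-3p and miR-126-5p differed by 0.14 ± 0.10 and 0.04 ± 0.14. miR-802 differed by -0.01 ± 0.23, miR-21 by 0.70 ± 0.28 (adjusted p = 0.218), miR-122 by 0.04 ± 0.05, miR-200b by 0.17 ± 0.17 and miR-429 by 0.15 ± 0.13. Centring the arrays on the median of the miRNAs above the floor moved the median of all miRNAs by 0.13 in this contrast, by 0.11 for phenobarbital in CTNNB1KO and by 0.13 for the interaction. On that scale 29 miRNAs passed, 14 higher and 15 lower, and miR-34a differed by 3.72. The count rose to 40 (11 higher, 29 lower) without the 2 muscle-bearing arrays, where miR-31* did not pass, and to 35 (10 higher, 25 lower) among miRNAs above the floor and 49 (15 higher, 34 lower) with array weights. miR-142-5p, miR-144 and miR-541 lost their calls without any of 5, 3 and 3 single arrays (highest adjusted p = 0.107, 0.0762 and 0.0807).

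The interaction tested whether the phenobarbital effect differed between genotypes. As measured it did for 7 miRNAs, all of them Dlk1-Dio3 members that rose in WT and showed less response in CTNNB1KO. All 7 averaged under the floor in WT controls and in both CTNNB1KO groups. The test thus rested largely on the WT phenobarbital group, and a rise below the floor in CTNNB1KO would not be seen. The difference in response was -2.003 ± 0.21 for miR-376b (limma adjusted p = 9.84e-06), -1.84 ± 0.28 for miR-154* (adjusted p = 0.00111) and -1.20 ± 0.22 for miR-127 (adjusted p = 0.00681). It was -1.05 ± 0.20 for miR-379, -0.95 ± 0.19 for miR-377, -0.62 ± 0.14 for miR-376a and -0.61 ± 0.14 for miR-411, which lay under the floor in every group. As a list the Dlk1-Dio3 miRNAs passed (camera adjusted p = 1.14e-07, and 0.0147 with an estimated correlation), with 7 of 75 members lower and 68 not passing. Adjusted over the list alone 18 were lower and 1 was higher. Without the 2 muscle-bearing arrays, a choice made after seeing the data, the camera adjusted p was 3.57e-05, and 0.0987 with an estimated correlation.

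No other list passed the interaction test, the closest being the erythroid markers (adjusted p = 0.165). miR-802, which rose with phenobarbital in WT alone, did not pass the test of the difference (-0.67 ± 0.32, adjusted p = 0.608; -0.95 and 0.0479 without CTNNB1KO control replicate 2), nor did miR-34a (1.34 ± 0.68), miR-21 (0.85 ± 0.40), miR-122 (0.18 ± 0.07) or miR-541 (-0.27 ± 0.10). Across the miRNAs above the floor outside the cluster, the phenobarbital effects in WT and CTNNB1KO, which share no array, had a Pearson correlation of 0.014 and a Spearman correlation of -0.026 (miRNAs are not independent replicates). The interaction count was 13 without WT phenobarbital replicate 1, 4 with median-centred arrays (1 of them miR-122), 20 with array weights and 2 with an unmoderated linear model. miR-376a and miR-411 lost their calls without any of 9 and 8 single arrays (highest adjusted p = 0.099 and 0.0941).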

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

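The tests of stellate cells, of miR-494 against miR-1224 and against the largest correlation, of the hepatocyte share and of muscle tissue, the counts of dim features and the leukocyte means of the splits were chosen after the results they bear on were seen.

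Some arrays stood far from the other 3 of their group, by the ratio of the gap to the range; of 191 such tests 16 passed, where chance gives about 9.55. On WT phenobarbital replicate 1, Dlk1-Dio3 miRNAs were lower than on the other 3 arrays: miR-127 at 4.11 (others from 4.87), miR-154 at 3.73, miR-299* at 3.72, miR-377 at 3.86 and the mean of the 12 members above the floor at 4.28 (others 4.83 to 4.94). The same array had miR-133b at 3.53 and a mean of the miR-99, miR-100 and miR-125 families of 5.89, both higher than the rest. WT phenobarbital replicate 2 had miR-200a at 3.82 (others 4.11 to 4.13), and WT control replicate 2 had a let-7 mean of 9.44. CTNNB1KO control replicate 2 had miR-34a, and with it the miR-34 list mean, at 9.41 (others 6.35 to 6.65) and a mean of the miR-17 and miR-92 paralogs of 5.60 (others 6.22 to 6.26). CTNNB1KO control replicate 3 had miR-494 at 9.68 (others 7.03 to 7.16), and replicate 4 had miR-31* at 5.35. CTNNB1KO phenobarbital replicate 3 had miR-200b at 4.42, and replicate 4 had a biliary or epithelial mean of 4.68 (others from 5.13).

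The measured phenobarbital effect differed between genotypes for 7 Dlk1-Dio3 miRNAs in limma's interaction test: miR-376b by -2.003, miR-154* by -1.84, miR-127 by -1.20, miR-379 by -1.05, miR-377 by -0.95, miR-376a by -0.62 and miR-411 by -0.61. All 7 averaged under the floor in both CTNNB1KO groups, where a rise below it would not be seen. The list differed with a median of -0.85 over its 12 members above the floor, 11 of which passed the floor in WT with phenobarbital alone. Of 100 splits of the arrays within genotype, the real one included, 4 gave 7 or more calls, and the highest other split gave 12. That share lies just under 0.05 and comes from a draw of the possible splits. It was not adjusted over the contrasts, so chance is not firmly excluded.

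The rise of the Dlk1-Dio3 miRNAs in WT was set against 2 technical explanations. Many of the members start near background, where between-array scaling could lift dim features. The 422 features outside the cluster that were dim in WT controls had a median log2 difference of -0.0022. RMA as usually run holds the median of so many features near 0, so that median cannot decide on scaling. The single values show less: none of the 422 passed, and their highest difference was 0.40, against 2.14 among dim cluster members. Of the 74 cluster members that were dim in WT controls 16 passed, with a median of 0.079 over all 74. A larger share of stellate or mesenchymal cells would raise their markers, whose 7 members above the floor had a median of -0.14 (SE 0.05 of their mean). Only 1 of the 35 splits of the 8 WT arrays, the real one, gave 17 calls and the highest other gave 4. With 35 splits no smaller share is possible. It was not adjusted over the contrasts, so chance is unlikely but not firmly excluded. A response of hepatocytes to phenobarbital that may depend on Ctnnb1 also stays open, a hypothesis found and tested on the same arrays. Why WT phenobarbital replicate 1 responded less is open too (without it the mean difference of the 12 members was 1.15).

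miR-494 is encoded in the Dlk1-Dio3 cluster but differed by 0.75 with phenobarbital in WT and by -1.60 in CTNNB1KO, passing in neither. CTNNB1KO control replicate 3, at 9.68, carries much of this gap: without it the difference in CTNNB1KO was -0.95. Without the same array miR-494 passed for genotype under phenobarbital (-1.28, limma adjusted p = 0.0218, against 0.179 with all arrays). Its deviations from the group means had a correlation of -0.063 with those of the other cluster members above the floor (Pearson; permutation p = 0.757; Spearman rho = -0.053, p = 0.83; r = 0.046 without the 2 farthest arrays; 16 arrays). These members averaged above the floor on 4 arrays only, so the value cannot show whether control is shared. The correlation with miR-1224, a feature outside the cluster, was 0.795 (p = 0.0015; rho = 0.709, p = 0.007; r = 0.915 without the 2 farthest arrays; adjusted p = 0.003 over the 2 relations), but the largest correlation over all features above the floor outside the cluster reached that value by chance with p = 0.311. Neither explanation was settled, and no biological explanation was tested.

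Markers of other cell types differed between genotypes, and 2 explanations were tested. A lower hepatocyte share alone would raise all other markers. In CTNNB1KO controls the leukocyte mean shifted by 0.60 and the stellate mean by 0.22, and the biliary or epithelial mean was 5.04 against 4.59. The erythroid mean shifted by -1.41, which differed from the leukocyte shift by -2.02 (exact permutation p = 0.0286, the smallest possible, n = 4 per group). A lower share alone would not give this erythroid fall. Erythroid miRNAs may also follow residual blood, so a lower share is not excluded. Striated muscle tissue in CTNNB1KO phenobarbital replicates 1 and 2 may account for their miR-1, miR-133a and miR-133b. The excess of the 3 was 5.18, 3.69 and 4.88 times larger on replicate 1 than on replicate 2, factors that differ by at most 1.41-fold. Of the other muscle members, miR-133a* was at 3.98 and 3.36 on these replicates, but miR-206 went the other way (3.45 and 4.08). On both replicates miR-208a, miR-208b and miR-499 lay under the floor. Residual blood and infiltrating leukocytes were not tested, and genotype stays open. For genotype in controls 1 of 35 splits, the real one, gave 5 calls (highest other 0), and under phenobarbital 1 of 35 gave 23 (highest other 0). These shares are the smallest possible and were not adjusted over the contrasts, so chance is unlikely but not firmly excluded for either.

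For phenobarbital in CTNNB1KO the real count was 0, so all 35 splits give at least as many and the count says nothing about chance. The highest other count was 12, reached by 2 splits: CTNNB1KO controls 1 and 2 with phenobarbital replicates 3 and 4 against the rest, and controls 1, 3 and 4 with phenobarbital replicate 1 against the rest. Most of the other splits gave 0, and the highest of 34 counts was not set against a null, so a structure among these 8 arrays that does not follow diet was not established. The first split parts the 4 arrays with leukocyte means of 6.15 to 6.68 from the 4 with 5.16 to 5.70. The second does not part them in this way, and the cause of neither was tested.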

How the results depend on the processing

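Leaving out the 2 muscle-bearing arrays, the same with an estimated correlation, and the annotated cluster membership were chosen after seeing the data; the other alternatives were set in advance. No named miRNA that passed changed sign under any alternative; of up to 43 such calls, between 0 and 9 lost significance per setting, the most in the unmoderated linear model. The cause was not tested except where fewer features or arrays were used. Among miRNAs above the floor (fewer tests), 8 passed for genotype in controls and 35 under phenobarbital. Array weights gave 29 for phenobarbital in WT, 9 and 49 for genotype without and with phenobarbital, and 20 for the interaction. Genotype in controls gave 3 with quantile normalization and 3 with its own 2 groups only. The interaction gave 4 with median-centred arrays and 2 with the unmoderated model. Without the muscle-bearing arrays (2 arrays left in that group) 1 passed for phenobarbital in CTNNB1KO and 40 for genotype under phenobarbital; lists that passed were 2 and, for the interaction, 3, and the muscle list reversed to a mean of -0.032. With an estimated correlation as well, 0, 1, 1 and 0 lists passed for phenobarbital in CTNNB1KO, genotype in controls, genotype under phenobarbital and the interaction, where the Dlk1-Dio3 list had an adjusted p of 0.0987.

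With an estimated correlation, 0 lists passed for phenobarbital in CTNNB1KO, 1 for genotype in controls and 1 under phenobarbital; fry gave 0 in the first. With camera on miRNAs above the floor, 4 and 2 lists passed for genotype in controls and under phenobarbital. As a per-array median over the 12 features above the floor, the cluster difference was 0.017 for phenobarbital in CTNNB1KO. For genotype in controls it was -0.21 (exact permutation p = 0.0286, the smallest possible and not adjusted, n = 4). Of these 12, 11 lay under the floor in every group but WT with phenobarbital, so both values compare background levels.

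Leaving out each array in turn gave 13 to 18 miRNAs for phenobarbital in WT, 0 to 1 in CTNNB1KO, 3 to 7 for genotype in controls, 19 to 34 under phenobarbital and 5 to 13 for the interaction. Mean differences of the 12 cluster members above the floor ranged over 0.93 to 1.15, -0.14 to -0.07, -0.13 to -0.05 and -1.34 to -1.12 for the 4 contrasts in that order. For phenobarbital in WT their exact permutation p was 0.0571 without any 1 WT control array and 0.0286 without any 1 phenobarbital array. Of these 12, 11 passed the floor in WT with phenobarbital alone. The rise thus in part chose them, and these p-values are no independent test of it. Replicate numbers did not pair the arrays: the 24 same-number pairs had a mean residual correlation of -0.03 (-0.45 to 0.40), 6 were over 0.1, and 3 of 16 arrays correlated best with their own number. With the replicate block the counts were 17, 0, 4, 23 and 7. The slide block was not run. Signal over background limits the Dlk1-Dio3 fold sizes, since control levels lay under the floor of 3.98.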

Other observations

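The values without the 2 muscle-bearing arrays in this part come from an alternative chosen after seeing the data, the tests of miR-34a with leukocytes as a covariate were chosen after its level was seen, and the lists other than leukocytes were set against miR-34a without an expectation stated first.

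With the 2 muscle-bearing arrays left out, the remaining 2 CTNNB1KO phenobarbital arrays differed from the 4 WT phenobarbital arrays in several miRNAs that had not passed with all 4 arrays. The arrays kept, replicates 3 and 4, had higher leukocyte means than those left out (6.68 and 6.65 against 5.36 and 5.70) and lower erythroid (6.30 and 6.46 against 7.46 and 7.05) and hepatocyte-abundant means (7.88 and 7.68 against 8.11 and 8.12), and replicate 4 had the fewest features over the floor (100). The differences below thus follow in part from which arrays were left out. At the preset correlation the leukocyte list rose (camera adjusted p = 0.000183; adjusted p = 0.123 with an estimated correlation), the erythroid list fell (adjusted p = 0.000133; adjusted p = 0.0905 with an estimated correlation) and the hepatocyte-abundant list fell (adjusted p = 0.000431; adjusted p = 0.261 with an estimated correlation), so none of the 3 passed with an estimated correlation. The Dlk1-Dio3 list fell under both (adjusted p = 5.52e-07; adjusted p = 0.0374 with an estimated correlation), and the stellate or mesenchymal list passed under neither (adjusted p = 0.056 and 0.261). Of leukocyte members, miR-223 rose by 2.20 ± 0.43, miR-142-3p by 2.14 ± 0.44, miR-142-5p by 1.73 ± 0.23 and miR-146a by 1.03 ± 0.29 in limma's test (log2 difference ± SE), and of erythroid members miR-144 fell by 2.07 ± 0.26 and miR-451 by 1.13 ± 0.30. The mesenchymal members miR-199a-3p (1.21 ± 0.27) and miR-199a-5p (0.60 ± 0.15) rose, and the hepatocyte-abundant members miR-455 (-1.02 ± 0.28), miR-101b (-0.75 ± 0.19), miR-365 (-0.73 ± 0.18) and miR-30d (-0.73 ± 0.17) and also miR-27b (-0.95 ± 0.20) fell. These miRNAs were named after their values were seen.

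miR-21, an abundant miRNA often raised in liver tumours, was lower in all 4 WT phenobarbital arrays than in all 4 WT controls (12.09 ± 0.20 against 12.90 ± 0.39) without passing in limma's test. It passed with array weights (-0.91, adjusted p = 0.0108), with the 2 groups alone (adjusted p = 0.0124) and without CTNNB1KO control replicate 2 (adjusted p = 0.034), and its adjusted p over the other settings and single arrays left out lay between 0.0844 and 0.585. None of the 39 viral features passed in any of the 5 contrasts (195 limma tests, 9 with an unadjusted p under 0.05, smallest adjusted p = 0.0707).

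One hypothesis concerned miR-34a, which varied widely among CTNNB1KO livers. If its level followed the leukocyte content of the sample, its deviations from the group means would follow those of the leukocyte list. Over the 8 CTNNB1KO arrays they did (Pearson r = 0.792, permutation p = 0.0016; Spearman rho = 0.905, p = 0.0016; adjusted p = 0.008 over 5 relations; r = 0.799 without the 2 farthest arrays). The stellate list had r = 0.758 (p = 0.0161, rho = 0.762, p = 0.0304, adjusted p = 0.0402), which fell to 0.092 without the 2 farthest arrays and so rests on them, while erythroid (r = -0.63, rho = -0.643), hepatocyte-abundant (r = -0.698, rho = -0.619) and biliary markers (r = -0.292, rho = -0.19) had adjusted permutation p-values of 0.0547, 0.0552 and 0.366. The value of 0.792 is consistent with miR-34a and leukocyte markers varying together among CTNNB1KO livers, and the cause was not tested.

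The difference of miR-34a between genotypes was also fitted with the leukocyte mean as a covariate in limma. Under phenobarbital the difference went from 3.59 ± 0.48 to 2.32 ± 0.43 (adjusted p = 0.00276). Every CTNNB1KO phenobarbital array had a leukocyte mean (5.36 to 6.68) above every WT array (highest 5.30). The fit thus reached beyond the WT range, and a list mean measures leukocyte content imperfectly. Whether leukocytes account for the whole difference under phenobarbital was therefore not settled. In controls the difference went from 2.25 ± 0.48 to 1.48 ± 0.37 (adjusted p = 0.0603). The call ended there because the difference became smaller, so this stays open for controls too. CTNNB1KO control replicates 3 and 4 had leukocyte means of 5.16 and 5.24, within the range of WT arrays (highest 5.30), and miR-34a at 6.35 and 6.42, above every WT array (highest 5.11).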
